A study of Homo sapiens with 32 samples.

How the data were processed

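RNA was measured in human presomitic mesoderm cells, the paraxial tissue that forms somites, derived from 201B7-based induced pluripotent stem cells that carry a luciferase reporter of the segmentation clock gene HES7. Per the labels' protocols, primitive streak cells were induced first, then presomitic mesoderm cells, which were split into dishes during that step. Luminescence was followed in a separate sample while the dishes for RNA were frozen at successive times. The labels describe 2 independent sets of 16 samples. Each time point within a set is a single library, so the error of a fitted value comes from the scatter of the 16 libraries around a smooth curve and not from repeated dishes at the same minute. Whether the dishes of a set came from one starting culture is not stated, so p-values measure the spread between these dishes only.

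The authors deposited whole-number read counts per gene, not normalized, in a table of 19904 rows named by gene symbol. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, cutadapt 1.14, HISAT2 2.1.0 and HTSeq 0.6.1, with genome build hg38. The gene annotation, the strand setting of the counting and the treatment of reads shared between copies of a gene are not given in the sources used here. Overlapping genes, antisense partners and near-identical copies can therefore share or lose counts. Per the labels' protocols, total RNA was extracted with an RNeasy kit and libraries were made on the NeoPrep system. The row named LUCIFERASE is the reporter. It entered the fits and the library sizes used in them, but it was left out of the numbers of genes, the totals given here and the adjustment of p-values. Its share of the counts of a library ranged from 0.0264% to 0.124%. Each of the 32 columns matched the label of one sample, and 0 columns were left unmapped.

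Total counts per library ranged from 26754339 to 38436995 in set 1 and from 21158584 to 37644778 in set 2. At that depth 15888 to 16349 genes had a count in a library, and the 10 most abundant genes took 3.61% to 5.29% of the counts. No pair of libraries of a set agreed within sampling noise. The chi-square per degree of freedom over genes with at least 20 counts in a pair was 2.48 or more.

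Genes with low counts were removed with filterByExpr on set, which left 13902 genes. Counts were scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Rhythm was tested with a cosine and a sine of period 300 min, the approximate 5 h period known for the human clock, over a linear and quadratic time trend within each set. Phase was free in each set, and the 4 cosine and sine coefficients were tested together. Each set was also fitted alone. A gene was called reproducible when the joint test passed, the unadjusted p was below 0.05 in each set alone, and its lag to HES7 differed between sets by at most 37.5 min. Lag is the fitted peak time minus that of HES7 in the same set. A mean lag within 50 min of 0 was called in phase and one over 100 min away antiphase, with leading or lagging between. Peak-to-trough change is the height of the fitted wave in log2, averaged over the sets, with a standard error from the fitted covariance.

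Slow change was tested as 1 linear slope shared by both sets, in log2 per 300 min, with cosine and sine as covariates, and called when both sets had the same sign. Set 2 minus set 1 was tested with linear time as covariate. A rhythm that differs between sets was tested as an interaction on time aligned to the HES7 peak. Lists of genes were tested for reproducible genes by a one-sided Fisher exact test against the other tested genes, and for direction, with HES7 left out for the in-phase component, with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. P-values were adjusted over the 26 lists. Genes were matched to GENCODE version 29 on GRCh38 for coordinates and GC content, and 18935 rows matched one gene.

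The genes named were fixed by rule. These are HES7, the 10 in-phase, 6 antiphase and 6 leading or lagging reproducible genes with the largest peak-to-trough change at a mean of at least 1 CPM (counts scaled to library size), up to 4 members of each list with the smallest adjusted p, and every reproducible member of the Notch, Wnt and FGF lists. Genes with other reasons to be named are marked as chosen after their values were seen. For slow change the rule took the 8 genes that rose and the 8 that fell most, and up to 4 members of each list. For the difference between sets it took the 3 genes highest and the 3 lowest. Y-linked genes and XIST were left out, and some genes that the rule names are not reported here. The groups, tests, lists, rule and a list of alternatives were fixed before the data were examined. Those alternatives were size factors by the RLE method, no filter and a filter at a mean of 5 CPM, DESeq2 1.42.0 and limma-voom, linear and cubic trends, other periods, other lag tolerances, shared phases, other covariates, omission of early time points and omission of each sample. A correction for GC content, omission of 3 libraries and some further periods and references were added after the data were seen.

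The fits were tested on simulated counts for 13864 genes. For the joint rhythm test, 88% of genes with a simulated peak-to-trough change of 0.5 log2 and 99% of those with 1 log2 were recovered, and 4.58% of calls were false. For the reproducible genes these shares were 87%, 99% and 0.533%, with a median lag error of 5.35 min. For slow change, 98% of simulated slopes of 0.3 log2 were recovered and 4.39% of calls were false. For the difference between sets, 98.5% of simulated changes of 0.5 log2 were recovered and 3.43% of calls were false. All these shares and the lag error describe the simulated counts and need not hold for the measured libraries. There, HES7 was fitted best at 367 min with the quadratic trend. The first component of the residuals after the trend followed GC content across genes (absolute r = 0.821).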

Results

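To find genes that vary with the human segmentation clock, the oscillator that times somite formation, gene expression was followed in reporter-carrying presomitic mesoderm cells. Set 1 held 16 libraries taken from 330 to 975 min on the time scale of the labels, 42 to 45 min apart. Set 2 held 16 libraries from 380 to 1040 min, 40 to 50 min apart. Total counts ranged from 21158584 to 38436995 per library. The sets were independent experiments, and each is 2.15 or 2.2 cycles long at the period of 300 min used in the test.

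HES7, the Notch-driven repressor at the core of the clock and the gene of the reporter, rose and fell in both sets. It is annotated as ENSG00000179111, on chromosome 17 from 8120590 to 8124092 on the minus strand (hg38). Its level ranged from 138 to 410 CPM (counts scaled to library size) in set 1 and from 90.9 to 399 CPM in set 2. The fitted peak-to-trough change was 1.07 log2 in set 1 and 1.26 log2 in set 2, with a mean of 1.16 ± 0.18 (SE, 16 libraries per set), or 2.24-fold (edgeR quasi-likelihood test, adjusted p = 0.00643). The reporter transcript varied with it, with lags of 2.83 and 7.17 min and a change of 1.11 ± 0.18 log2 (p = 8.5e-05). The SE of the reporter peak alone was 6.92 min in set 1 and 12.2 min in set 2, so these lags cannot be told from 0. In set 2 the HES7 peak came later on the label time scale: the fitted peak was at 184 min of the 300 min cycle in set 1 and at 248 min in set 2. LFNG, a glycosyltransferase that modifies Notch receptors (ENSG00000106003, chromosome 7, 2512529 to 2529177), varied by 1.19 ± 0.16 log2 with lags of -6.48 and -7.22 min (adjusted p = 0.00246). DKK1, a secreted Wnt antagonist (ENSG00000107984, chromosome 10, 52314296 to 52318042), moved in the opposite phase, with lags of 143 and 140 min and a change of 1.31 ± 0.17 log2 (adjusted p = 0.000707).

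**Figure D1:**
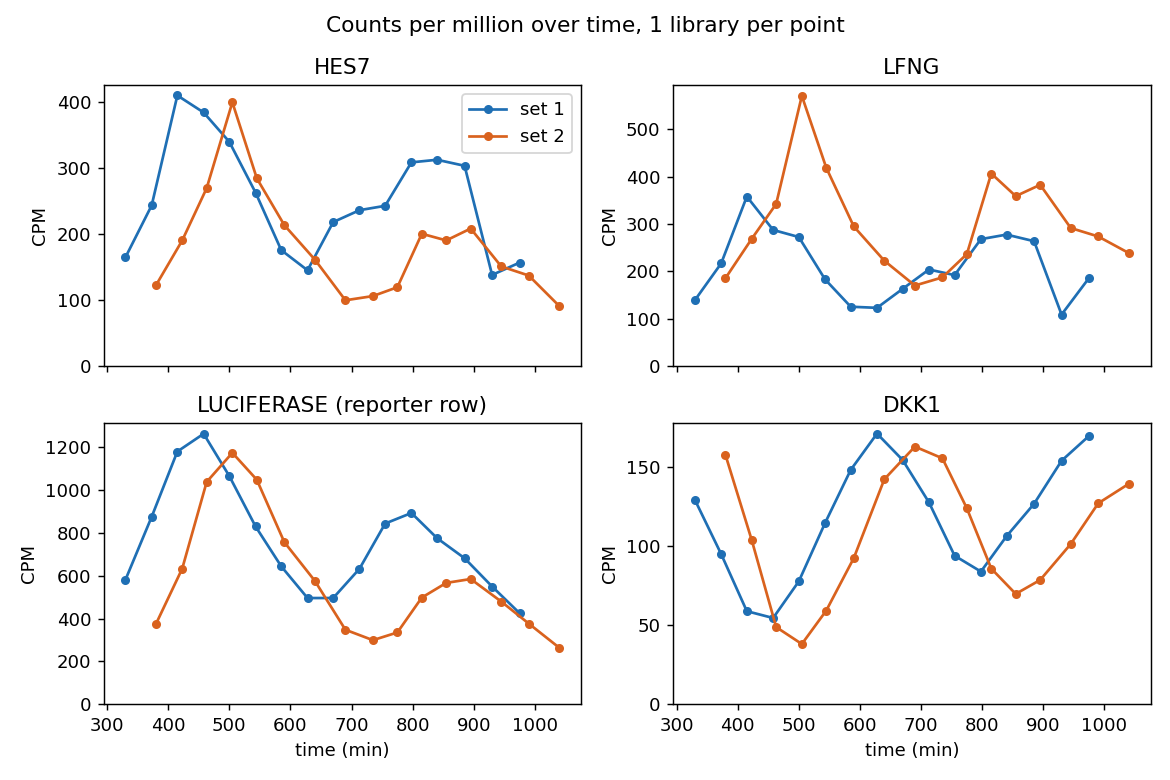
CPM (vertical axes, from 0) against time in minutes for HES7, LFNG, the reporter row and DKK1, 1 library per point, lines joining the libraries of a set. The HES7 maximum lies at 415 min in set 1 and 505 min in set 2, where DKK1 is low, and the DKK1 maximum at 628 and 690 min.

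Across the 13902 genes tested, 852 were rhythmic in the joint test of both sets. The number depends on the period and the trend: at 360 min it was 3286, with a cubic trend at 300 min it was 2227, and at 270 min it was 0, with 1240 genes at an unadjusted p below 0.05. HES7 itself was fitted best at 367 min (95% interval 335 to 437 min) with the quadratic trend, and its peak-to-trough change at 360 min was 1.31 log2. Of 883 genes with an unadjusted p below 0.05 in each set, against 434 expected from independent lists, 72.3% had lags within 37.5 min of each other, where evenly spread lags would give 25%. Lags were not evenly spread, and the lags of 2 different genes, 1 from each set, were that close in 27.2% of pairs, a comparison chosen after seeing the data. Of the 245 genes outside that range, 235 had a smaller lag in set 2. The share with close lags changed with the setting. It was 91.1% of 989 such genes with a GC offset, chosen after seeing the data. At 360 min, with the limit scaled to that cycle, it was 82.6% of 1567. With a cubic trend it was 67.3% of 1200, and without the 3 libraries with the steepest relation to GC content 65.6% of 967. The cause of the shared direction was not tested. Leaving out 1 library moved the joint number to between 521 (without set 2 replicate 8) and 2052 (without set 1 replicate 16), with 1707 without set 1 replicate 1 and 1280 without set 1 replicate 3. Set 1 alone gave 225 rhythmic genes and set 2 alone 326, with 73 in common where independent lists would share 5.28.

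**Figure D2:**
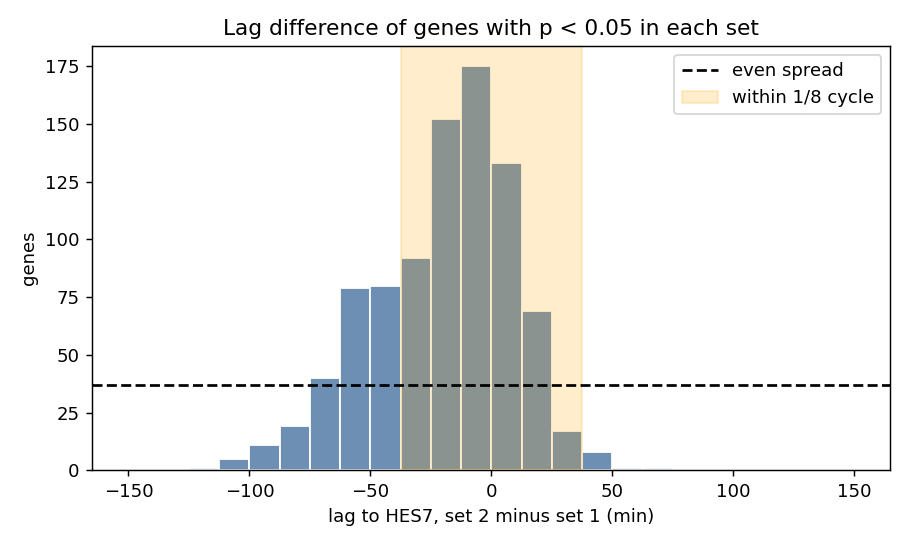
Number of genes (vertical axis) by the difference in lag to HES7, set 2 minus set 1, in minutes (horizontal axis), for the 883 genes with p below 0.05 in each set. The dashed line is an even spread, and the band is the 37.5 min allowed on either side, which holds 638 genes.

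**Figure D3:**
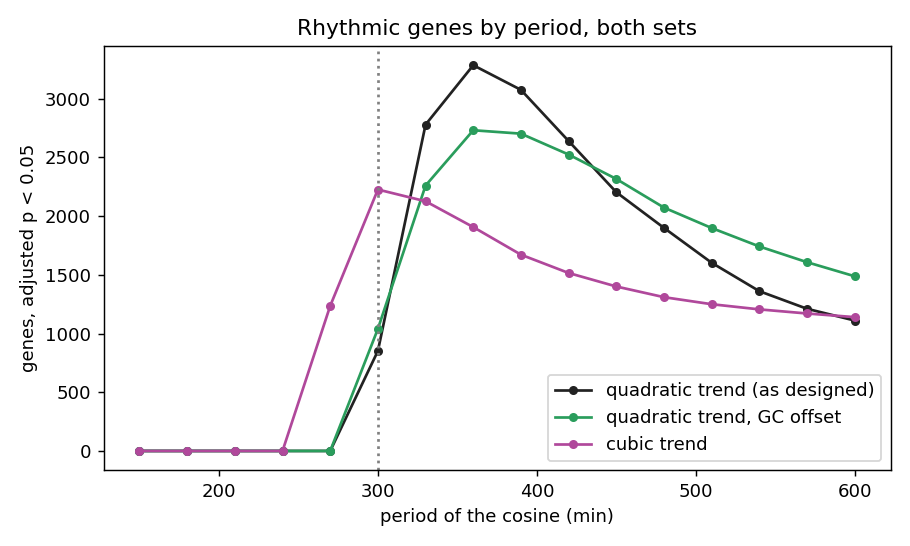
Genes with an adjusted p below 0.05 (vertical axis) against the period of the cosine in minutes, with the quadratic trend, the quadratic trend with a GC offset and the cubic trend. The first peaks at 360 min with 3286 genes, the second at 360 min with 2732 and the third at 300 min with 2227.

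There were 533 reproducible rhythmic genes, of which 340 were in phase with HES7, 114 in antiphase, 52 leading and 27 lagging. The median peak-to-trough change was 0.43 log2, and 29 genes exceeded 1 log2. The in-phase genes with the largest changes were led by NEUROG3, a proneural transcription factor (1.85 ± 0.25 log2, adjusted p = 0.000843), and ALOXE3, a lipoxygenase whose gene lies 1543 bp downstream of HES7 on the same strand (1.51 ± 0.18, adjusted p = 0.000303). RASD2, the endoderm and mesoderm regulator GATA6, SYNE3, the ERK phosphatase DUSP2, the kidney regulator PAX2 and the potassium channel KCNA1 followed with 1.41, 1.38, 1.23, 1.20, 1.17 and 1.15 log2. In antiphase to HES7, beside DKK1, were EGR1, an immediate early transcription factor (1.30 ± 0.22 log2, adjusted p = 0.00525), LRRTM1 at 1.20, the intermediate mesoderm gene OSR1 at 1.08, ZNF831 at 1.05 and the growth factor BMP3 at 0.94 log2. EGR3 (1.23 log2), ID1 (1.13), SOX18 (0.95), BHLHE40 (0.83) and KLF11 (0.80) led HES7 by a mean lag between -71.4 and -51.9 min, and JAKMIP1 (0.84) lagged by 54 min. Levels were low for RASD2, LRRTM1, JAKMIP1, SYNE3 and KCNA1, with means of 1.13, 1.15, 1.53, 1.58 and 1.82 CPM. ALOXE3 and NEUROG3 had 2.83 and 2.99 CPM, against 13.7 for GATA6, 16.7 for DUSP2 and 11.5 for PAX2. At 360 min, with limits scaled to that cycle, 1285 genes were reproducible, among them 505 of the 533. The split moved to 574 in phase, 239 in antiphase, 314 leading and 158 lagging, with 51 genes above 1 log2. With a cubic trend 789 were reproducible, 420 in phase, 155 in antiphase, 140 leading and 74 lagging. At 270 min none of the 533 was called. In-phase genes had a median GC content of 52.6% and antiphase genes of 46.9%, against 48.4% for all tested genes. The first component of the residuals after the trend held 23% of the variance, and its loadings followed GC content across genes (absolute r = 0.821, over genes, which are not independent replicates). With a GC offset, an alternative chosen after seeing the data, 752 genes were reproducible, including 483 of the 533, and at 360 min with a GC offset 52 exceeded 1 log2.

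Reproducible members of the Notch pathway were in phase with HES7 at 300 min. Of 25 tested, 8 were reproducible and in phase (Fisher exact test, adjusted p = 1.4e-05), and 9 passed the joint test over all genes against 12 adjusted over the list alone. They were HES7, LFNG, the feedback inhibitor NRARP (0.75 ± 0.10 log2), the receptor NOTCH1 (0.56 ± 0.07), the coactivator MAML3 (0.97 ± 0.13), the ligands DLL1 (0.82 ± 0.13) and JAG2 (0.70 ± 0.11), and the repressor HEYL (0.68 ± 0.12). The phase of HES7 is 0 by construction. Without HES7, an alternative chosen after seeing the data, 7 of 24 were reproducible and in phase (adjusted p = 0.000118). At 360 min, with limits scaled to that cycle, 11 were reproducible, 8 in phase and 3 leading or lagging, among them DLL1 with a mean lag of -64.6 min. With a cubic trend 7 were in phase and 3 leading or lagging, without the first 2 time points of each set 6 and 3, and without the 3 libraries with the steepest relation to GC content 6 and 1. The list moved up with the HES7 cosine by camera (adjusted p = 2.8e-06), and this was not called with an estimated correlation (adjusted p = 0.164 with an estimated correlation). By the same test the FGF and ERK list (adjusted p = 0.00635) and the hypoxia and glycolysis list (0.0369) moved up, and the G2/M list (0.00817) and the HOX genes (0.0369) moved down. None of these held, with adjusted p = 0.343, 0.413, 0.418 and 0.343 with an estimated correlation, in that order.

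At 300 min reproducible Wnt genes were either in phase with HES7 or in antiphase. Of 30 tested, 10 were reproducible, 4 in phase and 6 in antiphase (adjusted p = 6.2e-07), with 11 over all genes and 19 adjusted over the list alone. In antiphase were DKK1, the transcription factors SP5 (0.93 ± 0.18 log2) and SP8 (0.46), the scaffold DACT1 (0.47), the receptor TNFRSF19 (0.24) and the agonist RSPO3 (0.35). In phase were the inhibitor NKD1 (0.56 ± 0.10), the ligand WNT11 (0.62), the cyclin CCND1 (0.37 ± 0.04) and the effector LEF1 (0.26). At 360 min 18 were reproducible, 6 in phase, 8 in antiphase and 4 leading or lagging, and with a cubic trend 15, with 4, 7 and 4. AXIN2, a Wnt feedback gene chosen after its values were seen, did not pass at 300 min, with 0.37 log2 and an adjusted p of 0.0507. Its values at other periods are not reported here.

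Among targets and regulators of FGF and ERK signalling, 14 of 31 were reproducible (adjusted p = 2.4e-11), with 8 in phase, 3 in antiphase and 3 leading, and with 16 over all genes and 20 adjusted over the list alone. In phase were the inhibitors SPRY4 (0.37 ± 0.04 log2, adjusted p = 2.4e-05), SPRY1 (0.24) and SPRED2 (0.41), the phosphatases DUSP2, DUSP4 (0.70 ± 0.09) and DUSP5 (0.30), the ligand FGF18 (0.71 ± 0.10) and the factor ETV5 (0.23). EGR1, EGR2 (0.60) and FOS (0.52) were in antiphase, and IER3 (0.38), EGR3 and SNAI1 (0.28) led. DUSP6 had 0.05 log2 and an adjusted p of 0.668. Immediate early genes overlapped with these: 11 of 22 were reproducible (adjusted p = 9.9e-10), 4 in phase, 4 in antiphase and 3 leading or lagging, including FOSL2 (0.94), NR4A1 (0.82) and KLF6 (0.31), with 12 over all genes and 15 adjusted over the list alone.

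Of 28 tested genes that cycle in mouse presomitic mesoderm, 15 were reproducible (adjusted p = 2.9e-13), 7 in phase, 6 in antiphase and 2 leading or lagging, with 15 over all genes and 24 adjusted over the list alone. At 360 min 20 were reproducible, 6 in phase, 7 in antiphase and 7 leading or lagging, and with a cubic trend 20, with 7, 7 and 6. HES1, a Notch target chosen after its values were seen, did not pass (0.76 ± 0.21 log2, adjusted p = 0.150). Among presomitic mesoderm markers 7 of 23 were reproducible (adjusted p = 7.3e-05), with MSGN1 (0.59 ± 0.08) in antiphase and RIPPLY2 (0.57 ± 0.08) leading, and 7 passed both over all genes and adjusted over the list alone. The rest were HES7, LFNG, DLL1, SP5 and RSPO3, which the Notch or Wnt lists also hold. The mouse cyclic list also shares members with the Notch, Wnt and FGF lists, so these are not separate enrichments. Without HES7, an alternative chosen after seeing the data, 14 of 27 cyclic genes and 6 of 22 presomitic markers were reproducible (Fisher exact test, adjusted p = 4.03e-12 and 0.000585). Smaller lists also passed: intermediate mesoderm markers with 3 of 6 (PAX2, OSR1 and EYA1, adjusted p = 0.00382, 3 over all genes and 4 adjusted over the list alone), HOX genes with 5 of 23 (among them HOXD1, HOXA5 and HOXB9, adjusted p = 0.00501, 5 and 5), endoderm markers with 3 of 9 (GATA6, GATA4 and PRDM1, adjusted p = 0.0114, 3 and 5), lateral plate and cardiac markers with 3 of 10 (GATA4, GATA5 and GATA6, adjusted p = 0.0143, 4 and 5), TGF-beta and BMP targets with 4 of 20 (ID1, SKI, SKIL and TGIF1, adjusted p = 0.0150, 7 and 12) and somite markers with 3 of 13 (among them EPHA4 and FST, adjusted p = 0.0261, 4 and 7). SKIL was named after its values were seen. GATA6 and GATA4 are in both the endoderm and the lateral plate lists. GATA5 had a mean of only 0.51 CPM and was not reproducible at 360 min. Without the 3 libraries with the steepest relation to GC content (set 1 replicates 11 and 15, and set 2 replicate 3, an alternative chosen after seeing the data), the lateral plate, TGF-beta and somite lists no longer passed (adjusted p = 0.130, 0.106 and 0.177). At 360 min the endoderm, lateral plate and HOX lists did not pass (adjusted p = 0.0804, 0.0938 and 0.0938). Without the first 2 time points of each set the endoderm and lateral plate lists did not pass (adjusted p = 0.441 and 0.454), and with a GC offset the somite list did not (adjusted p = 0.0600). The TGF-beta and BMP list held 10 reproducible members at 360 min and 8 with a cubic trend, and the somite list 6 and 5.

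**Figure D4:**
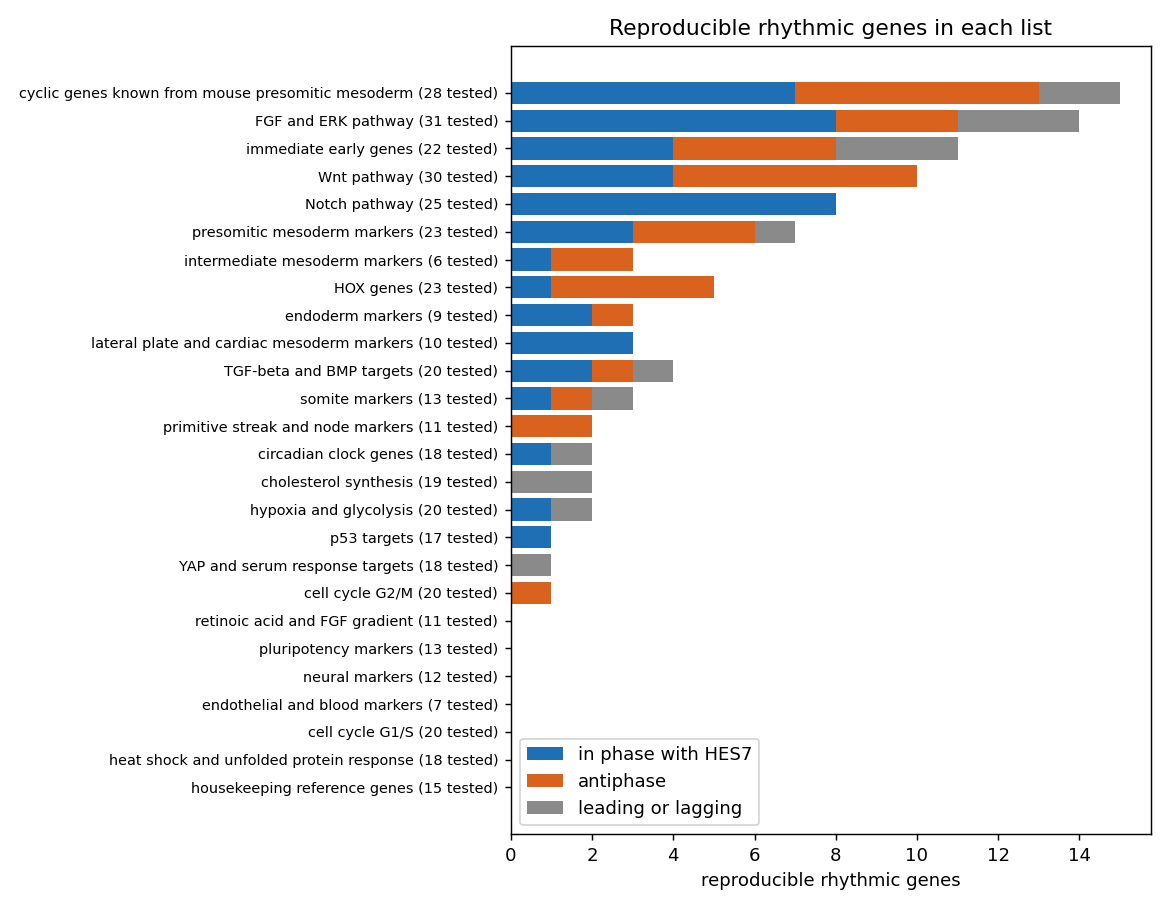
Number of reproducible rhythmic genes (horizontal axis) in each of the 26 lists, split into in phase with HES7, antiphase, and leading or lagging. The cyclic genes known from mouse hold 15 of 28 tested members, the FGF and ERK list 14 of 31.

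In the other lists no enrichment was called at 300 min with the quadratic trend and no GC offset. Primitive streak and node markers had 2 of 11 (EOMES and MIXL1, both in antiphase, adjusted p = 0.128), hypoxia and glycolysis genes 2 of 20 (PFKFB3 and HK2), cholesterol synthesis 2 of 19 (among them INSIG1), circadian clock genes 2 of 18 (BHLHE40 and PER1), YAP and serum response targets 1 of 18 (AMOTL2), G2/M genes 1 of 20 (AURKA) and p53 targets 1 of 17 (BTG2). In that order the joint test called 2, 2, 7, 3, 2, 2 and 1 of their members over all genes and 6, 4, 8, 8, 7, 7 and 4 adjusted over the list alone. At 360 min the circadian, hypoxia and primitive streak lists passed (adjusted p = 4.00e-05, 0.0200 and 0.0306), as they did with a cubic trend (adjusted p = 0.00110, 0.0391 and 0.0370). The cholesterol list passed with a cubic trend (adjusted p = 0.0370), and the circadian list with a GC offset at 300 min (adjusted p = 0.0307). At 360 min with a GC offset the circadian, hypoxia and primitive streak lists passed (adjusted p = 0.000160, 0.0371 and 0.0433), as did the YAP and serum response list (0.0255) and the retinoic acid and FGF gradient list with 4 of 11 (0.0433). Pluripotency (13 tested), neural (12), endothelial and blood (7), G1/S (20), heat shock and unfolded protein response (18), retinoic acid and FGF gradient (11) and housekeeping genes (15) had 0 reproducible members. Adjusted over the list alone, the joint test called 0, 0, 0, 0, 3, 1 and 2 of these. A rhythm that differs between the sets was called for 0 of 13902 genes (edgeR quasi-likelihood test, 1043 at an unadjusted p below 0.05). The absence of calls does not show that the rhythms of the sets were the same.

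Expression also changed steadily over the hours sampled. With 1 slope shared by both sets, 6439 genes were called, 3179 rising and 3260 falling. Few changes were large: 30 genes rose and 24 fell by more than 1 log2 per 300 min. The genes that rose most were VAV3, a guanine nucleotide exchange factor (1.56 ± 0.06 log2 per 300 min, adjusted p = 3.25e-20), KCNH5 (1.43), FAM19A1 (1.30), SAMD3 (1.24), IP6K3 (1.20), BMP3 (1.19), EBF2 (1.16) and XIRP1 (1.15). The genes that fell most were TNFRSF9 (-1.58 ± 0.09, adjusted p = 3.25e-16), EDN3 (-1.44), the epithelial cadherin CDH1 (-1.23), SLC18A3 (-1.20), PPP1R17 (-1.20), DRD2 (-1.15), AP1M2 (-1.13) and the pluripotency-associated TDGF1 (-1.13).

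Camera called 6 lists also with an estimated correlation, 5 of them with more falling than rising members. Among 13 pluripotency markers 9 fell and 1 rose, with POU5F1 at -0.87 ± 0.03, TDGF1 at -1.13 and SOX2 at -0.49 log2 per 300 min (camera adjusted p = 3.6e-08 and 0.00058 with an estimated correlation). Among 11 primitive streak and node markers 6 fell and 1 rose, including brachyury, listed as T, at -0.69 ± 0.02 and MIXL1 at -0.51 (adjusted p = 0.0013 and 0.035 with an estimated correlation). Neural markers had 8 falling and 2 rising of 12, with NKX1-2 at -0.64 and SOX3 at -0.57 (adjusted p = 0.00056 and 0.022 with an estimated correlation). Wnt genes had 14 falling and 4 rising of 30, with TCF7 at -0.52 and WNT8A at -0.54 (adjusted p = 1.5e-05 and 0.022 with an estimated correlation). Heat shock and unfolded protein response genes had 15 falling and 0 rising of 18, with ASNS at -0.47 and HSPB1 at -0.45 (adjusted p = 1.8e-07 and 0.0071 with an estimated correlation). Intermediate mesoderm markers went the other way, with 3 rising and 1 falling of 6, including EYA1 at 0.71 and SALL1 at 0.25 (adjusted p = 0.012 and 0.040 with an estimated correlation). Adjusted over the list alone, 10, 7, 11, 18, 15 and 4 of these lists' members were called, in the order given.

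**Figure D5:**
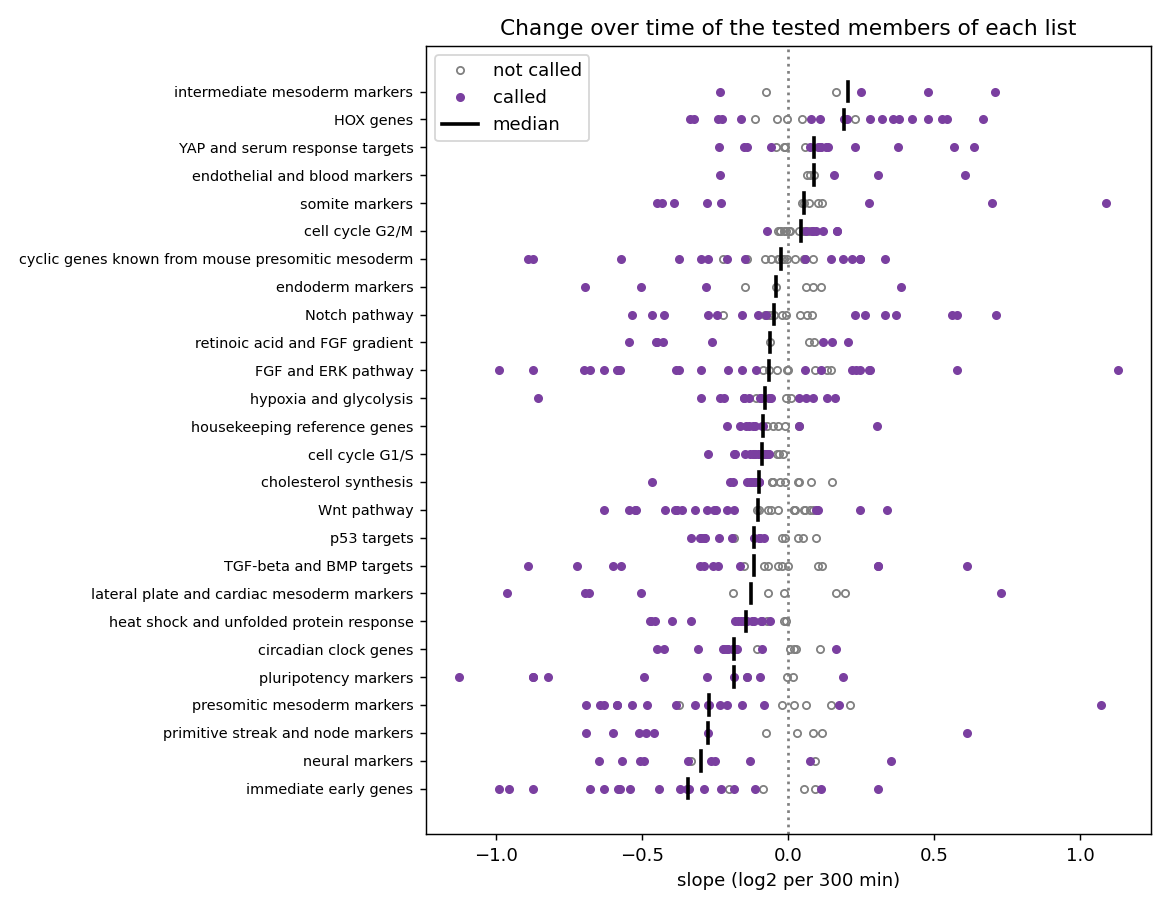
Slope in log2 per 300 min (horizontal axis) of each tested member of the 26 lists, filled where called, with the median of the list as a black bar. Immediate early genes have the lowest median, -0.34, and intermediate mesoderm markers the highest, 0.21.

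Several lists passed camera at the preset correlation and not with an estimated one. Immediate early genes had 16 falling and 2 rising of 22, with FOSL1 at -0.63, EGR2 at -0.68 and FOS at -0.58 (adjusted p = 1.7e-07 and 0.075 with an estimated correlation). Presomitic mesoderm markers had 15 falling and 2 rising of 23, with MSGN1 at -0.58, TBX6 at -0.48 and CDX2 at -0.58 (adjusted p = 6.7e-06 and 0.0831 with an estimated correlation). G1/S genes had 16 falling of 20, with UNG at -0.27 (adjusted p = 0.00011 and 0.053 with an estimated correlation). HOX genes had 13 rising and 5 falling of 23, with HOXC5 at 0.67 and HOXB4 at 0.53 (adjusted p = 0.0034 and 0.11 with an estimated correlation). Cholesterol synthesis had 10 falling of 19, p53 targets 11 of 17 (AEN at -0.30), TGF-beta and BMP targets 9 falling and 3 rising of 20 (ID2 at -0.89), hypoxia and glycolysis 11 and 5 of 20 (ADM at -0.85) and circadian clock genes 12 and 1 of 18 (PER2 at -0.22). Their adjusted p-values were 0.0056, 0.0056, 0.0118, 0.0145 and 0.0385, and 0.0516, 0.0870, 0.104, 0.161 and 0.277 with an estimated correlation. Endothelial and blood markers had 3 rising and 1 falling of 7, with TIE1 at 0.61 and KDR at 0.31 (adjusted p = 0.0496 and 0.0831 with an estimated correlation). Adjusted over the list alone, 19, 20, 16, 18, 10, 12, 12, 17, 13 and 4 members of these lists were called, in the order given.

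In the lists that camera did not call, somite markers included risers and fallers, TCF15 at 1.09 ± 0.05 and MEOX1 at 0.70 against EPHA4 at -0.43. Notch genes had 7 rising, with MAML2 at 0.71, and 8 falling, with JAG1 at -0.24, and their median of -0.05 and mean of 0.02 differed in sign. FGF and ERK genes had 9 rising, with FGF18 at 1.13 ± 0.07, and 14 falling. YAP and serum response targets had 10 rising and 4 falling of 18 (KRT18 at 0.23), G2/M genes 7 and 1 of 20 (MKI67 at 0.17), cyclic genes 7 and 8 of 28 (ID2 at -0.89), endoderm markers 1 and 3 of 9, lateral plate and cardiac markers 1 and 4 of 10 (NKX2-5 at -0.96), and retinoic acid and FGF gradient genes 3 and 5 of 11 (ALDH1A2 at -0.45). Housekeeping genes had 2 rising and 8 falling of 15, with ACTB at -0.16 and RPL13A at -0.21, against a median of 0.00 over all genes. Adjusted over the list alone, 8, 16, 25, 14, 8, 15, 4, 6, 8 and 11 members of these lists were called, in the order given.

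The sets differed from each other, which measures the difference between experiments. Between them 6274 genes were called, 3104 higher and 3170 lower in set 2, and 194 by more than 1 log2. SFRP5 (2.04 ± 0.05 log2), ANPEP (1.81 ± 0.05) and the somite boundary gene MESP2 (1.78 ± 0.13) were the highest in set 2 relative to set 1 by the rule. MTRNR2L8 (-3.81 ± 0.13), LCP1 (-2.75 ± 0.06) and KRT71 (-2.19 ± 0.05) were the lowest, and the adjusted p of MESP2, the highest of the 6, was 1.87e-13 (edgeR quasi-likelihood test). MTRNR2L8 belongs to a family of near-identical copies that resemble mitochondrial ribosomal RNA, so its counts are uncertain.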

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

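The GC offset, the omission of 3 libraries, the period grid to 480 min, 360 min with a GC offset and the lag to the reporter were chosen after seeing the data. Values below are numbers of genes, in the order both sets jointly, set 1, set 2, reproducible, against 852, 225, 326 and 533. At 240 and at 270 min all were 0 (edgeR; at an unadjusted p below 0.05, jointly 601 and 1240). At 330 min they were 2780, 2055, 943 and 1071. At 360 min, which is also where HES7 was fitted best on the grid to 360 min, its upper edge, they were 3286, 2563, 1143 and 1285. On the grid to 480 min HES7 was fitted best at 365 min, with 3268, 2546, 1153 and 1297. At 360 min with a GC offset they were 2732, 1272, 2085 and 1549. The first 3 were 2227, 1582 and 755 with a cubic trend. Without the first 2 time points of each set, which leaves fewer samples, the first 2 were 2189 and 1763. Single values moved to 148 in set 2 with a linear trend, 389 in set 1 with a GC offset, 584 in set 2 without the 3 libraries, and jointly to 1642 with the DESeq2 likelihood ratio test and 1298 with a phase shared on the label minutes. For these the cause was not tested.

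Leaving out 1 sample gave 521 to 2052 genes jointly, 398 to 666 reproducible and 6014 to 6692 rising or falling. Jointly it was 2052 without set 1 replicate 16, 1707 without set 1 replicate 1, 1280 without set 1 replicate 3 and 521 without set 2 replicate 8. Slow change and the difference between sets stayed within 1.5 times of 6439 and 6274 under the alternatives run. The time point numbers mark different minutes in the sets and were not taken to pair the samples: same-numbered samples correlated from -0.20 to 0.65, 14 of 16 pairs above 0.1, and from -0.25 to 0.27 after linear time, 11 of 16 above 0.1. With the number as a replicate block the difference between sets was 6792 genes, 6017 of them among the 6274. Of 85 named genes rhythmic at 300 min, 85 lost the call at 270 min, 49 in set 2 alone, 44 in set 1 alone, 15 with a linear trend, 4 with a GC offset and 1 at 360 min. Of 75 named genes reproducible at 300 min, 73 were so at 360 min with limits scaled to that cycle. Of these, 72 were in the same phase class and 1, DLL1, was leading in place of in phase. With RLE size factors, a linear trend, 330 min, 360 min or a GC offset none of the 75 moved between in phase and antiphase while passing the joint test. None of 113 named slopes changed sign with RLE size factors, without cosine and sine or with a GC offset. None did in 1 set alone either, but calls required the same sign in both sets, which largely fixed that outcome. The 113 were named for large slopes or small p in these data. At 21158584 counts or more per library, genes removed by the low-count filter were not tested.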

Other observations

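The tests of the set difference against the slope, of the HES7 period and of the genes beside HES7 were chosen after their results had been seen, as were the GC offset and 360 min with it. Circadian clock genes held 2 reproducible members of 18 at 300 min (adjusted p = 0.28, Fisher exact test) and 9 of 18 at 360 min (adjusted p = 4e-05). NR1D2, a repressor of the circadian loop, had 0.45 log2 at 300 min and was not reproducible there. EFNA1, an ephrin ligand that cycles in mouse, varied by 1.07 log2 in phase with HES7, and SKIL, a repressor of SMAD signalling, by 1.02 log2. Both were chosen after their values were seen.

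More genes were rhythmic at 360 min than at 300 min, 3286 against 852. GC bias of the libraries as the only cause is argued against, since with a GC offset the ratio of the counts was still 2.63. The counts were then 2732 at 360 min and 1040 at 300 min, so GC bias is not excluded as a cause of part of it. Curvature left by the quadratic trend may account for part of it, but the test does not isolate curvature. With a cubic trend the ratio fell to 0.856, with 1907 genes at 360 min and 2227 at 300 min. The 300 min count thus rose from 852 while the 360 min count fell from 3286. A clock slower than 300 min in these cultures may also contribute. The lower 95% bound of the HES7 period was 335 min with the quadratic trend and 346 min with the cubic one. With the quadratic trend it was 316 min for LFNG, 322 min for DKK1 and 362 min for the reporter. All come from the same libraries and are not separate evidence. Slow change shared in label minutes cannot be told apart. At 360 min, phases aligned to HES7 gave 1.38 times as many genes as label minutes, between the bounds set for either outcome. With a GC offset it was 1.62 times, which is past the bound against slow change. At 300 min the ratio was 0.951, with 1235 genes aligned to HES7 and 1298 on label minutes. The bounds were set for 360 min, and the spread of these ratios was not estimated.

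ALOXE3 and PER1, on either side of HES7, varied in phase with it. ALOXE3 starts 1543 bp downstream on the same strand, and its change exceeded that of HES7 by 0.34 ± 0.26 log2, so transcription reading through from HES7 is a candidate explanation, which the counts do not test directly. For PER1 it is excluded, since PER1 starts upstream (-35916 bp in transcription order). For 3 of the 6 tested genes within 100 kb the in-phase change, plus 2 SE, was under 0.25 of that of HES7. That all of the 6 follow HES7 is therefore excluded. These 3, TMEM107, BORCS6 and AURKB, were the farthest of the 6, so a shorter range is not excluded. VAMP2, 35057 bp upstream and chosen after its values were seen, had an in-phase change of 0.29 log2. Its adjusted p was 0.0278 for the in-phase component and 0.107 in the joint test (edgeR quasi-likelihood test).

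The difference between the sets rose with the slope over time across genes (Pearson r = 0.43, Spearman 0.41, over genes, which are not independent replicates), and 80.7% of the 3609 genes called in both had the same sign. Set 2 may therefore be further along the same course of change for part of the difference. GC bias as its cause is argued against, since 7337 genes were called with a GC offset.

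Reordering tested whether samples assigned to sets or times at random would give as many genes. Random assignment is argued against for the set difference, slow change and the reproducible genes. It is argued against less clearly for the joint rhythmic count, which another order exceeded. Free reordering also breaks leftover drift and any correlation between neighbouring samples of a set, so neither is excluded. Random splits mix the sets, so they do not tell what set the sets apart. For the cosine and sine terms the number of orders was raised to 100 after a first part had been seen. Of 100 splits of the 32 samples, 1, the real one, gave 6274 genes between the sets, and the highest other gave 1208. Of 100 orders of the samples within sets, 1 gave 6439 genes with slow change, and the highest other gave 2640. Of 100 orders of the cosine and sine terms, 2 gave as many rhythmic genes jointly, the real one with 852 and another with 1054. Of the same 100, 1 gave 533 reproducible genes, and the highest other gave 38.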
